A study of Mus musculus with 6 samples.

How the data were processed

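Samples were placed in groups by the genotype and age in their labels: wild type and Fezf1 Fezf2 double knockout at E9.5, E10.5 and E12.5, 1 array each. Per the labels' protocols, forebrain was dissected by hand, total RNA was extracted with a phenol-based reagent and biotin was incorporated by in vitro transcription in a one-cycle procedure. Nothing in the labels says how many embryos went into an array. The deposited values are probe set intensity on a linear scale, made with MAS5 per the submitters' processing notes. A scaling target, detection calls and a software version are not given in the sources used here. Background correction and probe summary are part of MAS5 and could not be redone from the table.

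The deposited intensity values had not been scaled to a common level: the 2% trimmed mean of an array ran from 74.3 to 162. The plan written before the data were examined took the values as deposited. Because the arrays differed in level, quantile normalization (limma's normalizeQuantiles) became the main setting instead, before any gene was tested, and the values as deposited became an alternative. Without scaling, the median difference between genotypes was 0.08 at E9.5, 0.26 at E10.5 and 0.20 at E12.5 on the log2 scale over probe sets above the filter, and list medians below are given relative to the median of all tested genes. Values were taken as log2(signal + 6.50), the pseudocount being the lower quartile of all deposited values, so a fold change of a dim gene is understated. For single genes a difference of 1 on this scale is 2-fold.

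Probe sets were named through the platform annotation supplied with the table: 34958 name 1 gene symbol, 932 name several and 9211 none that is listed. Only the first kind was used for genes. Of those, 34754 matched an Entrez identifier in the RefSeq table of GRCm38.p6, with 0 symbols changed. That table served only for names and for gene order, and no coordinates were taken from it. A gene takes its brightest probe set over the 6 arrays, and beside a single-age difference the second-brightest is given where it goes the other way. Of 142 named genes, 77 have a second probe set, and in 21 of them it goes in the other direction, at least 2-fold apart from the brightest, at some age. Genes whose mean log2 value lay above the median of all probe sets were tested, 11097 of 18194.

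The genotype effect across ages was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend) on all 6 arrays with age as a block, which leaves 2 residual degrees of freedom (9.21 after moderation over genes). An effect present at a single age counts as error in this fit. The change from E9.5 to E12.5 came from the same fit. P-values were adjusted by Benjamini-Hochberg over the tested genes with a threshold of 0.05. They measure only the spread between these arrays. Errors given with a mean difference are limma's moderated SE, which draws on the spread of other genes and is not the SE of the 3 pairs alone. At a single age no test was made: genes were counted where the arrays differed at least 2-fold and the higher value lay above the median of all values (signal 24.0).

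The 24 gene lists were Notch signalling, proneural and basal progenitor, early neurons, neuroepithelial and radial glial progenitors, dorsal telencephalon, cortical neurons, Cajal-Retzius cells, cortical hem and roof plate, ventral telencephalon, prethalamus, thalamus with pretectum and midbrain, hypothalamus, rostral Fgf signalling, axon guidance, S phase, G2 and M phase, olfactory placode, eye and lens, surface ectoderm, head mesenchyme, endothelium, erythroid cells, macrophages and sex-linked genes. They were written before the data were examined. Some genes are in several lists, so the lists are not independent of each other. Hes5 and the Notch list were chosen knowing that the study of these mice had reported Hes5, so their direction is not independent evidence. Lists were tested with camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. Camera sets a list against the other tested genes, and fry against no change. The first of these was run without a variance trend at first, when 2 lists passed, and the trend was added after that result had been seen, to match the gene test, when 7 passed. Both counts are given. Per age, a list's median was placed among 10000 random lists matched on expression. Their genes were drawn independently from the same 2 arrays. Such lists hold neither the spread between arrays nor the correlation within a list, which camera estimated at -0.12 (sex-linked) to 0.74 (early neurons). For correlated lists the random spread is too narrow, and a percentile is a description and no test.

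Named genes were chosen by a rule fixed beforehand: Fezf1, Fezf2 and Hes5; across ages up to 10 genes passing in each direction, with free places given to genes different in one direction at all ages, by their smallest difference; at each age the 6 largest increases and decreases by the 2-fold rule; in each list the 4 tested members with the largest mean difference and any that passed; and for age the 10 largest changes each way. Clone-named symbols were passed over. Genes outside the rule (3830406C13Rik, Irx2, Irx3, Tcf7l2, Rora, Krt19 and list members given as examples) were named after their values were seen.

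Alternatives changed the pseudocount, the scaling, the filter, the probe set rule, the variance model, the age term, the pairs used, the set test and the size rule. Scaling to a common 2% trimmed mean was added after the data had been examined. The gene and list tests were tested on simulated data with 11097 genes, the real means, limma's moderated spreads, and 20 runs. For the genotype comparison, simulated log2 differences of 0.5, 1, 2 and 4 were called with the right sign in 57.1%, 93.6%, 100% and 100% of genes. There were 15.75 false calls per run among the unchanged genes, 8.24% of all calls, above the 5% that the threshold sets. Each run held 50 changed genes of each size, with the same difference at every age. The real fit called 8 genes, which makes its cut on the unadjusted p stricter. The shares above may therefore overstate what the real test could find. For gene lists across ages, camera called an 18-gene list shifted by 0.3 in 20 of 20 runs and 1.75% of unshifted lists, in simulations whose genes vary independently. Figures were drawn with matplotlib 3.10.9.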

Results

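Gene expression was measured in the rostral forebrain of mouse embryos that lacked Fezf1 and Fezf2, a pair of related zinc-finger transcription factors of the early forebrain, and of wild-type embryos. Tissue in front of the caudal end of the lateral ventricles was dissected by hand at embryonic days 9.5, 10.5 and 12.5 (E9.5, E10.5, E12.5). Total RNA was labelled with biotin and hybridised to Affymetrix mouse arrays, 1 array per genotype and age, 6 arrays in all. No group has a replicate, so a difference at a single age has no replicate check, and the only error for genotype is how the knockout minus wild-type difference varied over the 3 ages. Exactly 1 gene symbol is named by 34958 probe sets, giving 18194 genes. Of these, 11097 lay above the filter on dim genes and were tested. The median deposited signal per array ran from 14.2 in wild type at E10.5 to 37.1 in the knockout at E12.5. Across tested genes the wild-type and knockout arrays correlated at 0.985 at E9.5, 0.982 at E10.5 and 0.988 at E12.5, and the wild-type arrays of E9.5 and E12.5 at 0.823. These correlations are across genes, which are not independent replicates.

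The targeted genes were examined first. Fezf2 signal was 78.9, 146 and 249 in wild type at E9.5, E10.5 and E12.5, and 0.458, 0.904 and 1.66 in the knockout. On the log2(signal + pseudocount) scale, which understates the change of dim values, this was 12.3-fold, 20.6-fold and 31.3-fold lower. Fezf1 signal was 251, 143 and 174 in wild type and 97.7, 78.4 and 49.5 in the knockout, which was 2.47-fold, 1.76-fold and 3.22-fold lower. Each gene has 1 probe set. The sources used here do not say whether these probe sets lie inside the deleted part of either gene, so the Fezf1 signal left in the knockout neither supports nor contradicts the labels. Hes5, a transcriptional repressor induced by Notch signalling, was 3.23-fold higher in the knockout at E9.5 (signal 679 against 206) and 2.26-fold higher at E10.5 (848 against 371). At E12.5 it stood at 840 in the knockout and 968 in wild type. The second Hes5 probe set differed by 0.93, 0.59 and 0.45 on the log2 scale, higher in the knockout at every age. Hes5 did not pass the test across ages (0.89 ± 0.27 over 3 pairs, here and below with limma's moderated SE; adjusted p = 0.999).

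**Figure D1:**
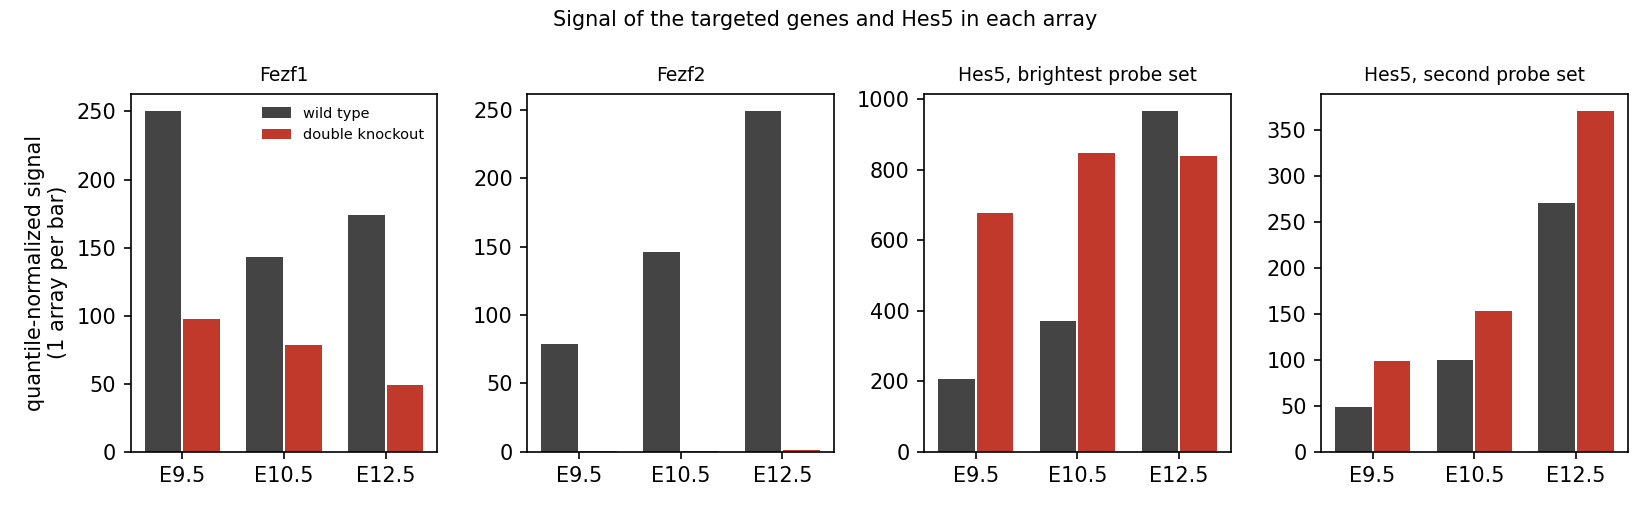
Quantile-normalized signal (y axis, starting at 0) of Fezf1, Fezf2 and both Hes5 probe sets by age (x axis), with 1 bar per array, wild type in grey and double knockout in red. Fezf2 in the knockout stays at or below 1.66 at all ages, Fezf1 is lower at all ages without reaching such a level, and the brightest Hes5 probe set is higher in the knockout at E9.5 and E10.5 only.

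The first comparison asked which genes differed between the genotypes in the same way at all 3 ages. Besides the targeted genes, 4 genes with a usual symbol fell in the knockout: Arf5, a small GTPase of membrane traffic, Rbm28, a nucleolar RNA-binding protein, Zfp503, a zinc-finger transcriptional repressor, and Apcdd1, an inhibitor of Wnt signalling. Their mean log2 differences were -1.42 ± 0.17, -0.77 ± 0.10, -0.63 ± 0.08 and -0.59 ± 0.07 (moderated SE, 3 pairs), each lower at all 3 ages, each with a limma adjusted p of 0.0440. Ano1, a calcium-activated chloride channel, rose by 0.93 ± 0.12 and was higher at all 3 ages (adjusted p = 0.0440). The clone-named gene 3830406C13Rik, which the rule for named genes leaves out and which is named after its values were seen, rose by 1.41 ± 0.13 (adjusted p = 0.00937), from signals of 45.2, 75.9 and 61.9 to 149, 192 and 173. Fezf2 fell by 4.32 ± 0.28 (adjusted p = 8.2e-04) and Fezf1 by 1.27 ± 0.17 (adjusted p = 0.0440). In all, 2 genes rose and 6 fell among 11097, and 521 genes had an unadjusted p under 0.05. That is fewer than this cut would pass on average if no gene differed. In the same direction at all 3 ages were 2750 genes (24.8%), about the share that signs unrelated between ages would give. A shared direction is therefore no evidence by itself. Second probe sets did not always follow: that of Rbm28 was higher in the knockout at all ages (0.20, 0.77 and 0.51), that of Zfp503 differed by 0.06, -0.00 and -0.56, and that of Apcdd1 by -0.06, -0.20 and -0.16. Those of 3830406C13Rik (0.70, 0.90 and 0.39) and Ano1 (1.48, 0.17 and 0.40) were higher throughout. In the gene order of GRCm38.p6, 3830406C13Rik lies 1 measured gene from Fezf2 and Zfp503 lies 54 from it, while Arf5 and Rbm28 lie 21 and 27 from Fezf1.

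Among genes that did not pass, those different in one direction at all ages included Calb2, which encodes the calcium-binding protein calretinin of Cajal-Retzius and other early neurons (-2.10, -2.30 and -0.92), Mmd2 (-1.19, -1.25 and -1.15), the LIM-homeobox gene Lhx1 (-1.06, -0.67 and -0.69; second probe set 0.45, -0.68 and -0.75) and the neurotrophin receptor gene Ntrk3 (-0.63, -0.69 and -0.72). On the other side stood Mnd1 (0.72, 0.73 and 0.75), Zdhhc12 (1.04, 0.71 and 0.69), A2m (0.75, 0.96 and 0.65), Ppfia3 (1.65, 0.64 and 0.70), Podn (0.54, 1 and 0.65), Crnde (0.54, 0.83 and 0.95), Slc45a3 (0.49, 0.49 and 1.07), Pdzd2 (0.58, 0.64 and 0.47) and Lmx1b (0.56, 1.03 and 1.02), whose second probe set gave -0.63, 0.04 and -0.16. Their adjusted p values lay between 0.146 for Calb2 and 0.999 for Pdzd2. The counts across ages rest on the settings: without a trend in the variance, without the E12.5 pair or without the age block, limma passed 0 genes, with 544, 485 and 24 at an unadjusted p under 0.05. Without the E9.5 pair it passed 22 higher and 50 lower genes, without the E10.5 pair 1 and 2, and on the values as deposited 16 and 4.

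Gene lists for regions, cell types and pathways were fixed beforehand, and each was set against all other tested genes over the 3 ages. The dorsal telencephalon list fell: 16 of its 18 tested members had a negative mean difference, 10 were lower at all 3 ages and 10 passed adjusted over the list alone, against 0 adjusted over all genes. Its largest members were Emx1 (-0.91 ± 0.31), Dmrta1 (-0.74 ± 0.19), Lhx2 (-0.64 ± 0.14) and Neurog2 (-0.63 ± 0.22), transcription factors of cortical progenitors. The second Emx1 probe set gave 0.21, -0.02 and -1.65. The list's mean lay 0.34 below that of all tested genes (-0.34; camera adjusted p = 1.4e-11), with adjusted p = 0.704 with an estimated correlation. The list of thalamus, pretectum and midbrain genes rose, with a mean 0.38 above all tested genes (camera adjusted p = 5.41e-07, adjusted p = 0.704 with an estimated correlation). Of its 18 tested members 15 had a positive mean difference, 8 were higher at all ages and 4 passed over the list alone: Irx3, Irx5, Pax3 and Tal2. No member of it passed over all genes. Its medians were 0.10 at E9.5, 0.18 at E10.5 and 1.05 at E12.5, and without the E12.5 pair its mean was 0.0959 (adjusted p = 0.0398).

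A further 5 lists passed camera with its preset correlation of 0.01. S-phase genes rose (14 of 18 positive, mean 0.07, adjusted p = 0.0147, and 0.704 with an estimated correlation), led by Tyms and Rrm1 (0.30 and 0.20), enzymes of nucleotide supply, and Mcm3 and Cdc6 (0.16 and 0.15), factors of replication origins. The second probe sets of Tyms (-0.15, -0.00 and -0.17) and Mcm3 (-0.04, -0.09 and -0.01) went the other way, and with the mean of all probe sets the list mean was 0.0234 (adjusted p = 0.317). The ventral telencephalon list rose (11 of 15 positive, mean 0.22, adjusted p = 0.0336, and 0.704 with an estimated correlation). Cortical hem and roof plate genes fell (10 of 16 negative, mean -0.12, adjusted p = 0.0295), as did progenitor genes (14 of 20 negative, mean -0.06, adjusted p = 0.0336) and early neuron genes (18 of 25 negative, mean -0.09, adjusted p = 0.0336). With an estimated correlation the last 3 had adjusted p = 0.704, 0.704 and 0.731. Lhx2, Pax6 and Gli3 are in both the progenitor and the dorsal telencephalon list. Lhx2 was the only progenitor gene passing over its list alone, so these results are not separate. Of the 24 lists, 7 passed camera with a trend in the variance and 2 without one, the dorsal telencephalon and the thalamus, pretectum and midbrain lists. The setting with a trend was settled after the result without it had been seen. No list passed with an estimated correlation (0 lists at an unadjusted p under 0.05) or by fry, which tests a list against no change and not against other genes (1 list at an unadjusted p under 0.05, smallest adjusted p = 0.602). Without the E10.5 pair the early neuron list passed in the other direction (mean 0.12, adjusted p = 0.0116) and the progenitor mean was 0.05 (adjusted p = 0.553), and without the E12.5 pair the hem and roof plate mean was 0.02 and the S-phase mean 0.0348 (adjusted p = 0.470). The ventral telencephalon mean was 0.0335 without the E9.5 pair (adjusted p = 0.536) and 0.23 without the E12.5 pair (adjusted p = 0.0926).

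**Figure D2:**
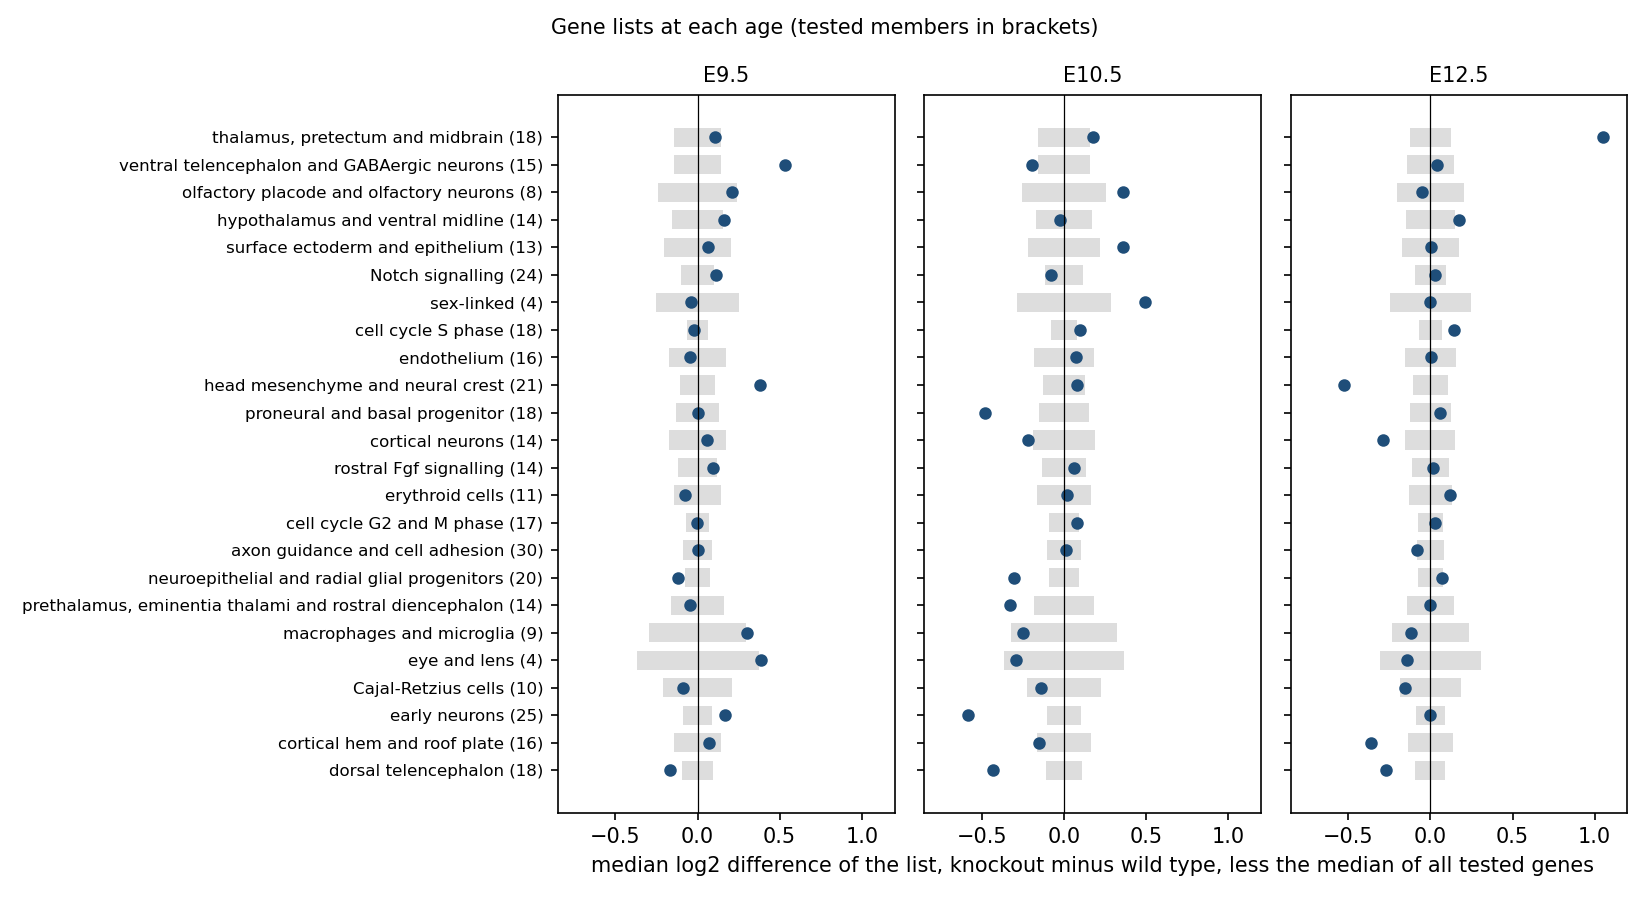
Median log2 difference, knockout minus wild type, of each gene list at each age, less the median of all tested genes (x axis), with the tested members in brackets. Points are lists and grey bars span 2 SD either side of 0 of the medians of 10000 random lists of the same size and expression. Genes of random lists were drawn independently, so the bars leave out correlation within a list. The thalamus, pretectum and midbrain list stands at 1.05 at E12.5, and the early neuron list at -0.58 at E10.5.

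At E9.5 genes of the ventral telencephalon were higher in the knockout. Their list had the largest median difference of any at this age, 0.53, above every one of 10000 random lists matched on size and expression. Of its 15 tested members 10 were higher, 2 of them at least 2-fold. Here and below, random lists leave out correlation within a list and the spread between arrays, so such a rank is no test. Lhx8, a LIM-homeobox gene of the ventral telencephalon, was 2.71 higher on the log2 scale, with a signal of 11.5 in wild type, below the median of all values, and 111 in the knockout. Dlx1, a homeobox gene of GABAergic neurons, was 1.69 higher (signals of 10.3 and 47.9) and Isl1 0.81 higher, although the second Isl1 probe set was 0.68 lower. Dorsal telencephalon genes were lower, with a median of -0.17 (percentile 0.04) and Dmrta1 at -0.72 and Lhx2 at -0.68. Early neuron genes had a median of 0.17 (percentile 99.96), with Stmn3 at 0.72 and its second probe set at 0.61. Head mesenchyme and neural crest genes, markers of tissue around the forebrain, also stood above every random list at this age (median 0.38, 19 of 21 members higher).

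Of the genes at least 2-fold different at E9.5, 161 were higher and 134 lower in the knockout. After Lhx8, the named ones were Utf1 (2.27), Ly6m (2.23), Rd3 (2.15), Cd209f (2.125) and Uroc1 (2.12), and on the lower side after Fezf2 stood Aire (-2.46), Cysrt1 (-2.30), Ltbp4 (-2.23), Cbr3 (-2.16) and Ddn (-2.12). The second probe sets of Utf1 (-0.66), Uroc1 (-0.39) and Cysrt1 (0.83) went the other way. Only 6.78% of these 295 genes had a signal over 100 in either array.

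At E10.5 neuronal and cortical genes were lower in the knockout. The early neuron list had a median of -0.58 and only 3 of its 25 members were higher. The proneural and basal progenitor list had a median of -0.48 and the dorsal telencephalon list one of -0.43, each below every random list. Tbr1 (-2.74), Eomes (-2.12) and Neurog2 (-1.48) are successive transcription factors of cortical neurogenesis, and Slc17a6 (-2.05) encodes a vesicular glutamate transporter. Emx1 was -1.98, Dmrta1 -1.25 and Lhx2 -1.06. Rtn1 was -1.10, Dcx, which encodes a microtubule protein of young neurons, -1.18, and Tagln3 -0.90. Progenitor genes had a median of -0.31 (below every random list), with Ddah1 at -0.68. Surface ectoderm genes (0.36, percentile 99.93, 12 of 13 higher) and olfactory placode genes (0.36, percentile 99.81, 5 of 8 higher) stood on the other side. Eya1 was at 0.58 and Eya4 at -0.77 (second probe set 0.13). Wnt6 was at 0.35, though the second Wnt6 probe set gave -0.31.

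The arrays of this age also differed in sex-linked transcripts. Xist, the RNA of the inactive X chromosome, had a signal of 573 in wild type and 11.7 in the knockout (-4.99), while the Y-linked genes Kdm5d, Uty and Eif2s3y were 0.58, 0.52 and 0.44 higher. The wild-type array also held Y-linked signal (102, 68.4 and 177 for these genes). The second Xist probe set gave -4.46 and that of Uty 0.81, while dim second probe sets of Kdm5d (-0.31) and Eif2s3y (-1.06) went the other way. In the deposited values, which are not scaled between arrays, the 4 poly-A control probe sets were 1.47-fold to 1.95-fold brighter in the knockout than in wild type. The trimmed mean of the knockout array was also higher, 91.2 against 74.3. By the 2-fold rule 149 genes were higher and 199 lower, 7.47% of them with a signal over 100. Higher were Ssmem1 (2.22), Cd180 (2.15), Prkcq (2.13), C2cd4b (2.09), Mmp9 (2.06) and Adamtsl2 (2.06), and lower, besides Xist, Fezf2 and Tbr1, were Creb3l3 (-2.66), Tnfrsf11a (-2.41) and Riiad1 (-2.38). The second probe sets of Mmp9 (-0.29) and Tnfrsf11a (0.44) went the other way. On the values as deposited the counts were 100 higher and 39 lower, and with a common trimmed mean 77 higher and 194 lower.

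At E12.5 genes of the caudal forebrain and midbrain were higher in the knockout. The thalamus, pretectum and midbrain list had a median of 1.05, above every random list, and 16 of its 18 members were higher, 10 of them at least 2-fold. Pax7, a paired-box gene of the dorsal midbrain, was 2.81 higher (signal 10.9 in wild type and 116 in the knockout), Irx5 1.67, Pax3 1.47 and Tal2 1. Irx2, Irx3 and Tcf7l2 stood at 1.53, 1.49 and 1.40, and Rora (-0.46, second probe set 0.09) and Nkx2-2 (-0.35) were lower. The second probe sets of Pax7 (1.198) and Tal2 (1.34) were higher too, that of Pax3 by 0.35. Olig3, a thalamic gene under the filter for tested genes, was 2.05 lower at this age and 2.19 lower at E10.5.

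Genes of the dorsal midline were lower at this age. Ttr, which encodes transthyretin and marks choroid plexus, had a signal of 2662 in wild type and 314 in the knockout (-3.06; second probe set -3.33), and Kcne2, a potassium channel subunit of choroid plexus, differed by -1.85. The hem and roof plate list had a median of -0.36 and the dorsal telencephalon list one of -0.27, both below every random list. The cortical neuron list stood at -0.29 (percentile 0.02) and head mesenchyme and neural crest genes at -0.52, with 2 of 21 members higher. The S-phase list had a median of 0.14, above every random list, with 17 of 18 members higher. By the 2-fold rule 58 genes were higher and 43 lower, 31.7% of them with a signal over 100. Among the named ones were Dbx1, a homeobox gene of neural progenitors (1.93), Scube2 (1.82), Smtnl2 (1.80), Bhlhe23 (1.73) and Ccdc130 (1.73), and, lower, Tnc (-1.90) and S100a8 (-1.77). The second probe set of Ccdc130 gave -0.23. The counts were 245 higher and 94 lower on the values as deposited, and 78 and 81 with a common trimmed mean.

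**Figure D3:**
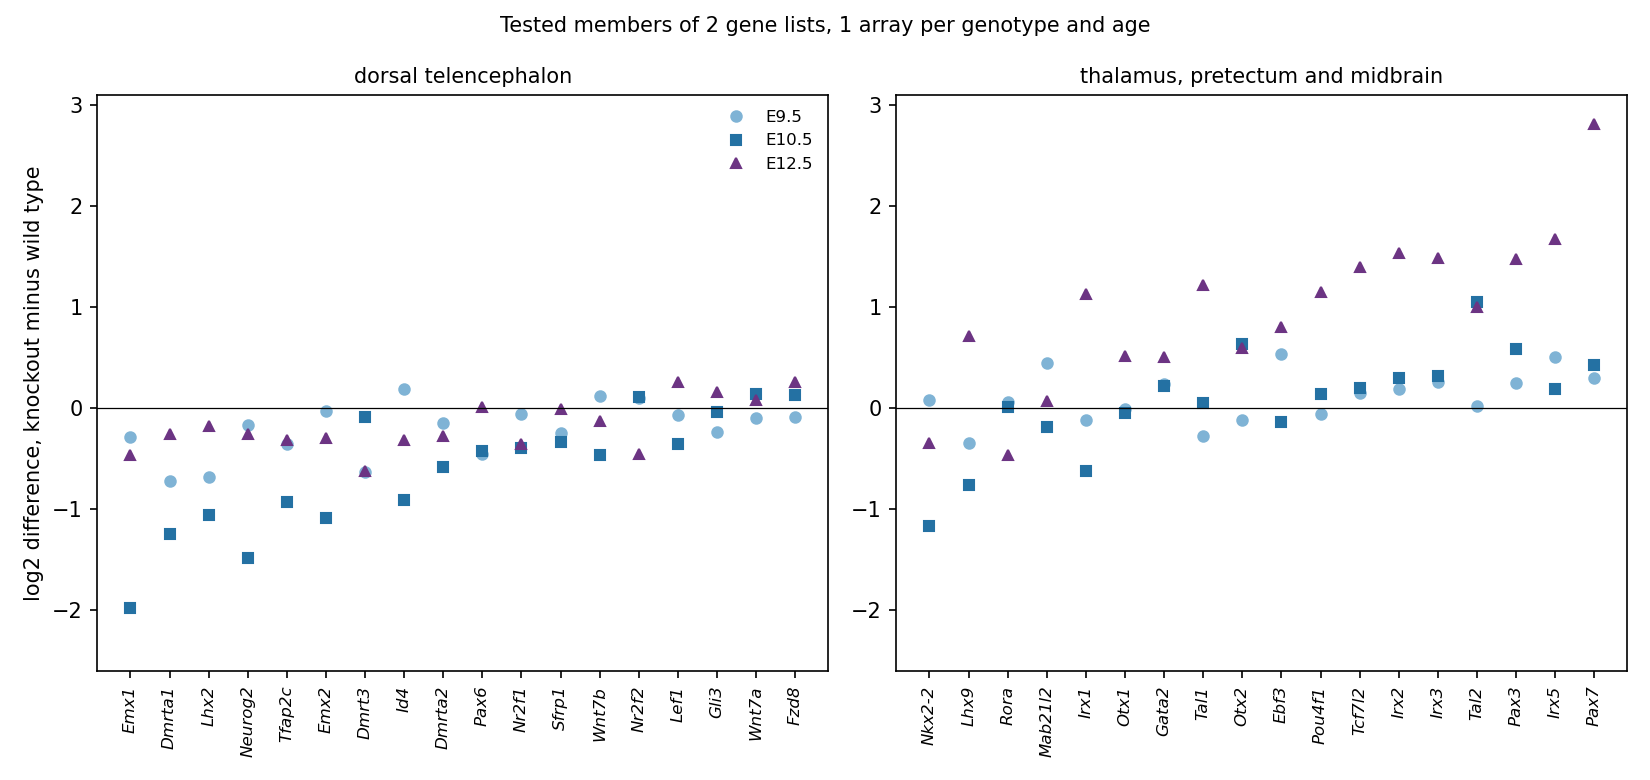
Log2 difference, knockout minus wild type (y axis), of each tested member of the dorsal telencephalon list (left) and of the thalamus, pretectum and midbrain list (right) at E9.5 (circles), E10.5 (squares) and E12.5 (triangles), 1 array per genotype and age. In the left panel the lowest values are squares (Emx1 at -1.98), and in the right panel the highest are triangles (Pax7 at 2.81).

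The differences were then compared between ages, where no array is shared. Beyond Fezf2 (lower) and 3830406C13Rik (higher), no gene was 2-fold different in one direction at all 3 ages with the brighter signal of each pair above 24.0. At E9.5 and E10.5 together, 8 genes were higher and 9 lower, where independent lists give 0.85 and 0.62. Among them were Hes5, Adamtsl2 and Krt19 (higher) and Calb2 and Arf5 (lower), and 11 genes went in opposite directions (1.49 by independent lists). The E9.5 and E12.5 pair shared 2 higher and 3 lower genes (0.386 and 0.136 by independent lists), and 7 went in opposite directions (0.465). The E10.5 and E12.5 pair shared 4 and 4 (0.260 and 0.277), with 3 opposite (0.609), including Tal2 and Lmx1b (higher) and Olig3 and Mmd2 (lower) among the shared. Across the 11097 tested genes the differences correlated at 0.04 between E9.5 and E10.5, 0.02 between E9.5 and E12.5 and 0.07 between E10.5 and E12.5. All of these are descriptions of 6 arrays, with no test.

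A further comparison asked whether genes that normally rise or fall with age differed in the knockout. At E10.5 the knockout difference correlated at -0.29 (Spearman -0.28) with the wild-type change from E9.5 to E12.5. The 1223 genes at least 2-fold higher at E12.5 than at E9.5 in wild type had a median knockout difference of -0.18, and the 1573 genes at least 2-fold lower one of 0.10. The same correlation was 0.04 at E9.5, against the wild-type change from E10.5 to E12.5, and -0.09 at E12.5, against that from E9.5 to E10.5.

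The last comparison asked which genes changed between E9.5 and E12.5 in both genotypes. Neuronal genes rose: all 25 tested members of the early neuron list and all 18 of the proneural list passed the test, with median log2 changes of 3.72 and 2.31. Dcx rose by 6.32, Islr2 by 5.77, Rtn1 by 5.69, Slc17a6 by 5.67, Nfia by 5.46, Mapt by 5.32, Map2 by 5.25, Celf5 by 5.17 and Dlx1 by 5.08. Ttr rose by 6.33. Of the genes that fell, Lin28a, which encodes an RNA-binding protein of early progenitors, changed by -6.18, Esrp1 by -5.32, Prtg by -5.17, Dsp by -5.07, Six6 by -4.97, Aldh1a3 by -4.91, Alx1 by -4.84, Cdh1 by -4.68 and Sall4 by -4.57. Xist also fell (-4.87), from signals of 725 in wild type and 453 in the knockout at E9.5 to 9.87 and 17.6 at E12.5. The Y-linked gene Uty stood at 89.8 and 96.3 at E9.5 and at 103.7 and 95.6 at E12.5. Eif2s3y, also Y-linked, stood at 168 and 194 at E9.5 and at 296 and 164 at E12.5. The sex of the embryos is not given. On these signals both E9.5 arrays appear to hold RNA of both sexes, and the E12.5 arrays mainly or only male RNA. No array of known female RNA gives the background of the Y-linked probe sets, so this is a reading and no test. The fall of Xist is therefore not read as a change with age. Surface ectoderm genes fell in 12 of 13 members (median -3.01), and head mesenchyme genes in 17 of 21 (median -1.84). In all, limma passed 2857 higher and 4103 lower genes at E12.5, and 16 lists passed camera with the preset correlation, 0 with an estimated one (adjusted p = 0.385 for early neurons and proneural genes). On the values as deposited the genes numbered 5438 higher and 1657 lower. The E9.5 arrays also had a hybridization control (BioC) 4.32-fold brighter than the other arrays and an Actb 3′ to 5′ ratio of 3.12 and 3.21 against 1.44 to 1.84. Between the E10.5 and E12.5 arrays, deposited BioC signal was 222 and 207 against 206 and 181, in wild type and knockout. Other controls were not alike: each poly-A control was brighter at E10.5 in both genotypes, with deposited Dap at 1706 and 2791 against 746 and 807. Deposited trimmed means of wild type were 74.3 and 139. After quantile normalization, wild-type signal at E10.5 and E12.5 was 131 and 1787 for Dcx, 189 and 1999 for Rtn1, and 306 and 2631 for Map2.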

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

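The test of neighbouring genes and the test of caudal tissue were chosen after the results they bear on had been seen. With 1 array per genotype and age, none of the differences between ages given here was tested.

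Of the 6 genes that passed across ages besides Fezf1 and Fezf2, 4 lie within 100 measured genes of one of them in the gene order, where 0.099 is the number their share of tested genes would give (exact one-sided hypergeometric p = 1.05e-06, a test chosen after the genes were seen). The mean absolute t of all 183 tested neighbours, the 4 included, was 1.17, against a mean of 0.854 over 1000 random pairs of windows, at percentile 100. With genes that passed left out it was 1, against a mean of 0.852 over the same random pairs, at percentile 99.9. A candidate explanation is an effect of the targeted loci, or of DNA from the targeted cells' strain that stayed around them. Differences in sequence under single probe sets may contribute: in the 3 called neighbours with a second probe set above the filter, the median ratio of its mean difference to that of the brightest was 0.265 (-0.65 for Rbm28 and 0.47 for 3830406C13Rik), between the bounds set beforehand, so a change in the transcript and a change in binding to 1 probe set cannot be told apart.

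The genes of thalamus, pretectum and midbrain were higher in the knockout at E12.5. The list's median was 0.995 or more under every other scaling, but it is taken relative to all tested genes, which cancels a factor per array, so this does not test scaling. Caudal tissue carried along with the dissected knockout piece may account for it, and the 88.9% of members that were higher are the pattern itself and no support. Such tissue would lower every telencephalic list by a like amount. These ran from -0.36 for hem and roof plate to 0.04 for the ventral telencephalon. That gap is above the 0.20 that random lists give as 2 SD, a spread that leaves out correlation within a list. Some ventral genes are also made in the diencephalon, so a dissection difference and a change of regional fate in the knockout cannot be told apart, and the latter was not tested.

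Neuronal genes were lower in the knockout at E10.5. The early neuron median was -0.610 or lower under every other scaling, a measure that cancels a factor per array as above and does not test scaling. Embryos at an earlier stage may account for it: early neuron genes were short of 13.8% of their wild-type change from E9.5 to E12.5. Outside all lists, 1492 falling genes were short of 7.70% of theirs and 1117 rising genes of 10.04%. The shortfall was therefore not limited to the listed neuronal genes. The ratio of falling to early neuron genes was 0.558 (0.409 to 0.737 by resampling genes), above the bound of 0.5 set beforehand, though its interval includes that bound. A delay caused by the genotype predicts the same and stays open, as does the sex of the embryos. Surface ectoderm genes, which fall with age, were also higher in the knockout at E10.5 (median 0.36, 12 of 13 members). Head mesenchyme genes, which fall too, had a median of 0.08 (14 of 21 members higher). The test on falling genes therefore cannot tell stage from a difference in the tissue dissected.

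Gene lists stood apart from random lists in opposite directions at different ages. The early neuron list had a median of 0.17 at E9.5 and -0.58 at E10.5. The ventral telencephalon list had medians of 0.53 at E9.5 and -0.19 at E10.5, and the head mesenchyme and neural crest list 0.38 at E9.5 and -0.52 at E12.5. Of the named genes, Cysrt1 was 2-fold different in opposite directions with the brighter signal above 24.0 each time, at -2.30, 1.40 and -1.41 at E9.5, E10.5 and E12.5, and its second probe set gave 0.83, -0.05 and 0.95. The poly-A control probe sets, which measure RNA added during labelling, had a median knockout to wild-type ratio of 1.77 at E10.5, 1.13 at E9.5 and 1.09 at E12.5. These ratios are of deposited values, without scaling between arrays. Of 10092 probe sets that do not name exactly 1 gene, control probe sets left out, 1 was at least 2-fold different in one direction at all ages by the same rule, with differences of -1.47, -1.2 and -1.32.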

How the results depend on the processing

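Over 21 settings, 2434 of 2785 recomputed values were labelled the same by rules fixed for each kind of value. Of the rest, 145 became weaker, 84 stronger, 110 moved and 12 reversed. For gene and list tests, a value that did not pass in the main setting was labelled the same even where its sign turned. Single genes across ages, most of which did not pass, hold 1297 of the same labels. Among counts 56 stayed the same, 31 became stronger and 52 weaker. Except where stated, the cause was not tested. Every alternative written down before the data were examined was run. Scaling to a common trimmed mean was chosen after seeing the data. The age block already pairs the arrays of 1 age, and the labels give no replicate numbers.

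Across ages 2 genes were higher and 6 lower. Higher genes numbered 1 with a pseudocount of 1, 16 as deposited, 1 with a common trimmed mean, 0 without a filter, 0 with the mean of all probe sets, 0 without a variance trend, 0 without the age block and 0 with a linear age term. Lower genes numbered 0, 4, 1, 1, 2, 0, 0 and 1 under the same settings, and 3 with arrays centred on their median. Leaving out 1 pair gave 0 to 22 higher and 0 to 50 lower genes: 22 and 50 without E9.5, 1 and 2 without E10.5, 0 and 0 without E12.5, each with fewer arrays. All 8 genes were among the 72 called without E9.5, and 5 of them among the 20 called as deposited. Fezf2 passed in 9 of the 12 alternatives in which it was tested, with adjusted p from 8.07e-14 to 0.305, and Fezf1 in 6 of 14, Ano1 and Arf5 in 5, and Rbm28, Zfp503 and Apcdd1 in 3. No direction of these 7 genes turned in these alternatives, though the mean difference of Rbm28 came to -0.136 in one of them. The second-brightest probe set alone was not among these alternatives. On it the mean difference of Rbm28 was 0.496, against -0.768 on the brightest, so its direction depends on the probe set.

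Counts at single ages followed the size rule, the filter and the pseudocount by construction. At E9.5, 161 higher and 134 lower genes became 529 and 426 at 1.5-fold, 46 and 34 at 3-fold, 560 and 487 without a filter, 25 and 18 with the brightest 33% of probe sets, and 38 and 32 with a pseudocount at the median. A pseudocount of 1 gave 209 lower genes. At E10.5, 149 and 199 became 440 and 674, 39 and 73, 633 and 733, 12 and 31, and 31 and 60 in the same order. There were 39 lower as deposited, 77 higher with a common trimmed mean and 97 higher with the mean of all probe sets. At E12.5, 58 and 43 became 249 and 245, 10 and 11, 318 and 280, 25 and 19, and 15 and 16. There were 245 and 94 as deposited, 81 lower with a common trimmed mean, 33 higher with the mean of all probe sets and 70 lower with a pseudocount of 1. From E9.5 to E12.5, 2857 higher and 4103 lower genes became 5438 and 1657 as deposited, and 1883 higher with a linear age term. Without the E10.5 pair they were 2940 and 4164. The share of higher calls moved by over 10 points as deposited across ages (80%), at E10.5 (71.9%), at E12.5 (72.3%) and with age (76.6%), from 25%, 42.8%, 57.4% and 41.0%. With a common trimmed mean it was 50% across ages and 28.4% at E10.5, and with arrays centred on their median 50% across ages.

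No list passed camera with an estimated correlation, or fry, which tests for a shift of the list up or down and not the mean relative to other genes. Relative means, which these settings leave as they are, with the adjusted p of camera and then of fry, were: dorsal telencephalon -0.34 (adjusted p = 0.704 and 0.602), thalamus, pretectum and midbrain 0.38 (0.704 and 0.681), S phase 0.0661 (0.704 and 0.68), hem and roof plate -0.12 (0.704 and 0.923), progenitors -0.0647 (0.704 and 0.943), ventral telencephalon 0.22 (0.704 and 0.942) and early neurons -0.0885 (0.731 and 0.968). Without a variance trend the last 5 did not pass. Of 14 alternatives the dorsal telencephalon list passed 12, from -0.41 to -0.21 without 1 pair, and the thalamus, pretectum and midbrain list 12, from 0.10 without E12.5 to 0.52. Progenitors did not pass as deposited or centred (-0.0436 each) or with a common trimmed mean (-0.0529), and ran from -0.13 to 0.0523 without 1 pair, turning without E10.5. Ventral telencephalon genes did not pass as deposited or centred (0.19 each), with a common trimmed mean (0.19) or without a filter (0.15), and ran from 0.0335 to 0.39 without 1 pair, not passing without E9.5 (0.0335) or E12.5 (0.23). Early neurons did not pass without a filter (-0.0841) and ran from -0.24 to 0.12, passing in the other direction without E10.5 (adjusted p = 0.0116). S phase did not pass with the mean of all probe sets (0.0234) or without E12.5 (0.0348), and ran from 0.0348 to 0.11. Hem and roof plate ran from -0.24 to 0.0243, turning without E12.5.

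Few other values were labelled reversed. The correlation of differences at E9.5 and E12.5 (0.02) was -0.00091 with a pseudocount of 1 and -0.0020 without a filter. The sex-linked median at E10.5 (0.50) was -0.35 with the mean of all probe sets. Second probe sets turned Utf1 (-0.66), Uroc1 (-0.39) and Cysrt1 (0.83) at E9.5, Mmp9 (-0.29) and Tnfrsf11a (0.44) at E10.5 and Ccdc130 (-0.23) at E12.5. That setting covered only the genes named for a difference at a single age. Of the 77 named genes with a second probe set, 21 had it in the other direction and at least 2-fold apart at some age, Rbm28 at every age.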

Other observations

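Several lists that did not pass across ages hold single genes of interest. The Notch list had a mean 0.06 above all tested genes (15 of 24 positive, camera adjusted p = 0.191), with Hes5 at 0.89, Lfng at 0.34 (second probe set -0.09, 1.46 and -0.40 by age) and Mib1 at 0.26, and Jag2, a Notch ligand gene, at -0.70. Fgf15, a growth factor gene of the early neural tube, was higher at all 3 ages (0.48, 0.47 and 1.18), while the rostral Fgf list had a mean of 0.09 (adjusted p = 0.191), with Spry4 at 0.31, Spry1 at 0.26 and Fgfr1 at -0.23. Cajal-Retzius genes had a mean of -0.26 (adjusted p = 0.0592), with Calb2, Lhx1 and Lhx5 passing over the list alone, and Ebf1 at 0.61. The prethalamus list stood at -0.21 (adjusted p = 0.206), cortical neurons at -0.13 (adjusted p = 0.206), where Nfia gave 0.40 (second probe set -0.45, -0.16 and -0.53) and Nfib -0.39, and proneural genes at -0.09 (adjusted p = 0.237), with Igsf8 at -0.29 and Elavl2 at -0.24. Hypothalamus genes stood at 0.12 (adjusted p = 0.206), with Six6 at 0.60 and Foxd1 at -0.74. Axon guidance genes stood at -0.04 (adjusted p = 0.410), with Epha4 at -0.42, Robo1 at 0.39, Pcdh8 at -0.37 and Plxna4 at -0.54 (second probe set 0.12, 0.46 and -1.33). G2 and M phase genes stood at 0.04 (adjusted p = 0.206), with Kif11 at 0.25 and Mki67 at 0.24.

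Lists for tissues other than neural tube were as follows. Olfactory placode genes had a mean of 0.18 and surface ectoderm genes 0.14 (adjusted p = 0.0571 each), with Eya2 at 0.28, Trp63 at 0.45 (second probe set -0.78, 0.22 and 0.16) and Cdh1 at 0.33. Head mesenchyme genes stood at -0.03 (adjusted p = 0.965), endothelial genes at 0.03 (adjusted p = 0.610), with Tie1 at 0.62 and Pecam1 at -0.47, and erythroid genes at 0.04 (adjusted p = 0.418), with Hba-x at 0.28. Macrophage genes stood at -0.01 and sex-linked genes at -0.35 (adjusted p = 0.965 each), and eye and lens genes, with 4 tested members, at 0.01 (adjusted p = 0.820), with Dct at 0.45. Xist signal was 725 and 453 in the E9.5 arrays of wild type and knockout, and 9.87 and 17.6 in those of E12.5, so only at E10.5 was Xist bright in one genotype and near background in the other.

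Other splits of the arrays bear on the tests across ages. The real split gave 8 genes, and the highest of the other 9 ways to part the 6 arrays into 3 and 3 gave 2, so 1 of the 10 splits gave as many genes. For gene lists the real split gave 7 and the highest other 12, and 6 of the 10 splits gave at least as many lists. Counting the real split and either direction, the dorsal telencephalon list passed in 7 of the 10 splits. The thalamus, pretectum and midbrain list passed in 6. With 10 splits the share cannot fall under 0.1, too few for a share under 0.05. Splits that part only 1 age come in pairs that give the same fit up to its sign, so these counts hold some fits repeatedly. Among splits that part every age, as the real split does, the smallest possible share is larger still. With age as a block, a split that parts the arrays of 1 age fits the genotype difference at that age, and the others mix the differences of 3 ages with unlike signs, so no other split is free of genotype.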
